A study of Mus musculus with 6 samples.

How the data were processed

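The data were 6 gene expression tables, 1 per library, from 3 ES and 3 XEN libraries of mouse total RNA sequenced on the BGISEQ-500 platform. Groups and replicate letters came from the sample titles. Per the submitters' processing notes, the authors used the mm9 genome build, Bowtie2, RSEM and DESeq2, with no versions, roles or order given. The deposited tables gave expected counts per gene in the authors' RSEM format, which are not all whole numbers, and the authors' FPKM values. The gene models were RefSeq protein-coding transcripts plus 6911 transcripts added by the authors, some in named genes and others in unnamed models. Genes with an added transcript took 30.48% to 34.78% of the counts of a library. No RefSeq non-coding transcript was listed. Each deposited table left out genes whose FPKM rounded to less than 0.01, and a gene absent from a table was taken as 0 counts. Of 17710 genes in any table, 12772 were in all 6 and 957 were unnamed models, which took 5.56% ± 0.11 of the counts in ES libraries and 4.25% ± 0.07 in XEN libraries. The tables used here hold values per gene, so transcript use of Pkm and other genes was not tested.

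Total expected counts ran from 20675311 to 22375875 per library, so that 3 counts in a single library came to 0.134 to 0.145 CPM before scaling. Expected counts were rounded to whole numbers. Genes were kept by filterByExpr on the groups, which left 13581 of them. Libraries were scaled by TMM, with factors from 1.04 to 1.05 in ES and 0.951 to 0.96 in XEN libraries. The comparison of XEN with ES cells used the edgeR quasi-likelihood F test with robust dispersion (edgeR 4.0.16 in R 4.3.3), group as the only term and Benjamini-Hochberg adjustment at 0.05, and glmTreat tested the same fit against a change of 2-fold. The common biological coefficient of variation was 4.75%. Fold changes are XEN over ES; errors of CPM are SDs over 3 libraries, and errors of log2 fold changes are standard errors from the spread of log2 CPM (prior count 2) in both groups. A gene with 0 counts in a group was given as a bound against 3 counts over the group, and a gene with 1 to 3 counts as a ratio of summed counts with an exact (Clopper-Pearson) 95% interval. No pair of libraries was alike within sampling noise, since the chi-square of their counts over its degrees of freedom was at least 2.34 within groups.

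Gene lists, tests, named-gene rule and most alternatives were set before the data were examined. There were 51 lists of identity, signalling, metabolic, mitochondrial, matrix, chromatin, cell cycle and other cell type genes, written from textbook knowledge, of which 49 had at least 3 tested members. The list for a state like that of 2-cell embryos had 1 tested member and the list of mtDNA-encoded genes had 0. Lists were compared with all other tested genes by camera (limma 3.58.1) on log2 CPM, with a preset correlation of 0.01 between genes. Camera was run again with an estimated correlation, where p rests on the 4 residual degrees of freedom of the 6 libraries. Fry tested each list against no change, without the other genes. Members were also counted by the gene test, adjusted over all genes and over the list alone. The balance of 19 pairs of related metabolic genes was tested by limma on the log2 ratio of CPM + 1. The share of counts of the mtDNA-encoded model was compared by an exact permutation test.

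Genes named in the text were chosen by rule: the 8 largest fold changes in each direction among called genes with symbols, non-overlapping groups and a mean of at least 20 CPM; 8 identity genes; of each list, up to 2 members with the largest change in each direction among called genes with a mean of at least 5 CPM, and the most abundant member; and the members of the gene pairs. Without the members of the gene pairs, the rule named 212 genes, of which 209 passed 0.05; the text gives a part of them. Genome positions are not given, since the reference annotation at hand (GRCm38) is of another build than mm9; chromosome membership was taken from it by gene identifier for 95% of tested genes.

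Alternatives were RLE, upper-quartile and no composition factors; no filter and a mean of at least 1 CPM; a replicate letter as a block; leaving out each library; the Wald test of DESeq2 1.42.0; limma-voom; limma-trend on log2(FPKM + 1); list members with a mean of at least 5 CPM or called by glmTreat; pseudocounts of 0.1 and 5 CPM and FPKM for the gene pairs; and leaving out the mtDNA-encoded model. Summing 732 unnamed models into the named gene of their orthology term, and leaving unnamed models out, were added after the data were seen. The pipeline was tested on simulated data for the comparison of XEN with ES cells, with 13581 genes of which 50 were changed at each fold: edgeR called in the right direction 31 of 50 genes changed 1.2-fold, 43 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 50 of 50 changed 4-fold, and called 19 of 13094 unchanged genes. At 4-fold, 46 of 50 passed glmTreat. In the simulation camera called a list of 20 genes raised 2-fold and did not call an unchanged list, and a chromosome raised 1.5-fold was recovered at a log2 change of 0.577. The simulation drew genes independently and left most of them unchanged, unlike the data. It therefore tests neither the preset correlation of camera nor the scaling where most genes change. Tables and figures were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.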

Results

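RNA was sequenced from 2 kinds of mouse cell line grown without feeder cells. Embryonic stem (ES) cells, which represent the pluripotent epiblast, were of strain 129/Ola and were kept on gelatin in serum-free medium with 2i inhibitors and LIF. Extraembryonic endoderm (XEN) cells, a self-renewing line type of the lineage that forms the yolk sac endoderm, were of strain ICR and were kept in RPMI1640 with serum. Each group held 3 libraries, named A, B and C. The ES libraries held 20675311, 21905479 and 22037793 expected counts and the XEN libraries 22375875, 22357053 and 21134720. Between 15846 and 15901 genes were listed per ES library and between 14589 and 14777 per XEN library. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread among these libraries, which may be technical. Strain, medium and cell type change together between the groups, as does expression from the Y chromosome, so no difference can be assigned to one of them.

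The series asks how XEN cells compare with ES cells in metabolism and mitochondria, and the identity genes were read first. Pou5f1 (gene 18999), the POU factor required for pluripotency, averaged 1063 ± 17.9 CPM, the counts scaled to library size (SD, n = 3), in ES cells and 0.353 ± 0.133 in XEN cells, a log2 fold change of -11.55 ± 0.25 (SE). Nanog (gene 71950) and Sox2 (gene 20674), both core pluripotency factors, fell from 831 ± 13.2 to 0.318 ± 0.0512 CPM and from 554 ± 6.72 to 0.190 ± 0.123 CPM. Gata4 (gene 14463), a zinc finger factor of the endoderm, rose from 2.31 ± 0.119 to 969 ± 23.9 CPM, and Gata6 (gene 14465), which specifies primitive endoderm, rose from 0.282 ± 0.0355 to 339.5 ± 7.54 CPM. Sox17 (gene 20671) and Sox7 (gene 20680), SOX factors of the same lineage, rose by log2 fold changes of 9.82 ± 0.17 and 10.72 ± 0.24. Pdgfra (gene 18595), a growth factor receptor used as a marker of primitive endoderm, rose from 0.679 ± 0.219 to 573 ± 32.0 CPM. For these 8 genes all 3 XEN libraries lay beyond all 3 ES libraries, and the adjusted p of the edgeR quasi-likelihood test ran from 1.03e-27 to 4.2e-23.

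**Figure D1:**
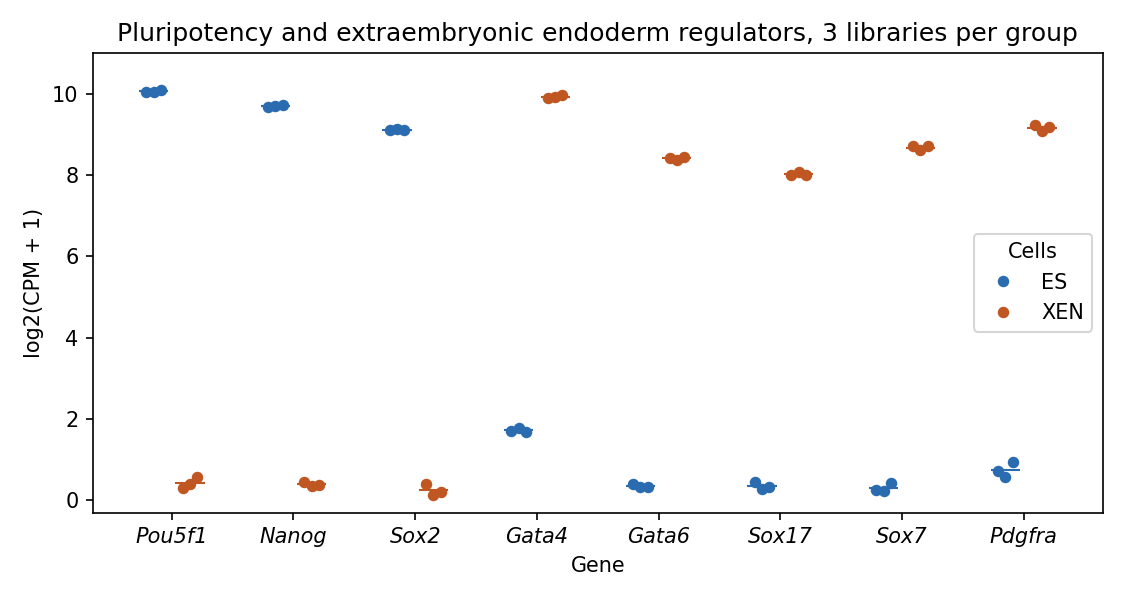
Expression of 8 regulators as log2(CPM + 1) in each of 3 ES libraries and 3 XEN libraries, with a point per library and a line at the group mean. Pou5f1, Nanog and Sox2 are high in ES libraries, with group means of 1063, 831 and 554 CPM, and the other genes are high in XEN libraries, where Gata4 averages 969 CPM.

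All 19 tested members of the extraembryonic endoderm list rose in XEN cells, over all genes and equally when adjusted over the list alone. Among them, Dab2, an endocytic adaptor, went from 1.17 ± 0.199 to 2525 ± 171 CPM and the endocytic receptor Cubn from 0.343 ± 0.167 to 1029 ± 227 CPM. The list ranked above other genes in camera with its preset correlation (adjusted p = 2.6e-07), while the adjusted p = 0.325 with an estimated correlation. All 15 members of the parietal endoderm list, 5 of them in both lists, rose as well (adjusted p = 6.43e-06, and adjusted p = 0.641 with an estimated correlation). They included Pth1r, the parathyroid hormone receptor, at 0.148 ± 0.109 and 682 ± 26.0 CPM, and the matrix protein gene Sparc at 238 ± 11.2 and 7790.0 ± 626 CPM. Of the 15 tested members of the visceral endoderm list, 12 rose and 3 fell, with a median log2 fold change of 6.36, or 6.25 with the member at 0 counts in ES cells set at its bound (adjusted p = 0.0174, and adjusted p = 0.765 with an estimated correlation). Spink1, a secreted protease inhibitor, had 1 count over the ES libraries and 70.4 ± 11 CPM in XEN cells, a ratio of 4781 with a 95% counting interval of 858 to 189000. Apoe, an apolipoprotein, fell by 1.14 on the log2 scale from 836 ± 26.5 to 379 ± 44.0 CPM, and Lefty1, a Nodal antagonist, had 4781 counts over the ES libraries and 1 over the XEN libraries. Afp, the fetal albumin homologue of visceral endoderm, chosen after its values were seen, was under the filter on low counts, with 7, 6 and 7 counts in the XEN libraries.

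In the naive pluripotency list 13 of 14 tested members fell and none rose (adjusted p = 0.000257, and adjusted p = 0.325 with an estimated correlation). Esrrb, an orphan nuclear receptor of naive cells, went from 987 ± 18.4 to 0.368 ± 0.114 CPM, and Dppa5a, an RNA-binding protein gene, from 865 ± 37.3 to 0.252 ± 0.163 CPM. In the general pluripotency list 9 members fell, 2 rose and 1 did not pass, and camera did not place the list apart from other genes (adjusted p = 0.101). The 2 that rose were Lin28a, an inhibitor of let-7 processing, at 184 ± 9.87 and 972 ± 10.5 CPM, and the zinc finger factor Sall4 at 210.3 ± 4.2 and 504 ± 3.82 CPM. Tdgf1, a Nodal co-receptor, fell from 519 ± 10.4 to 0.142 ± 0.0444 CPM. Of 6 tested members of the list for primed or formative epiblast, 4 fell and 2 rose. Its member Otx2, a homeobox factor, fell by 6.34 on the log2 scale. Foxd3, a forkhead factor, had 0 counts in every XEN library and was at least 301.8-fold lower there, and the methyltransferase gene Dnmt3b rose from 50.2 ± 0.547 to 219 ± 4.13 CPM.

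Most genes of matrix production and protein secretion rose as well, although the matrix list is not separate from the endoderm lists. Of 23 tested members of the basement membrane and collagen modification list, 19 rose and 3 fell (adjusted p = 7e-05, and adjusted p = 0.765 with an estimated correlation). Of these members 8 are also in an endoderm list, and of the other 15, 11 rose and 3 fell. The type IV collagen chains Col4a1 and Col4a2 went from 4.88 ± 0.534 to 6452 ± 336 CPM and from 1.87 ± 0.279 to 3049 ± 180.0 CPM. The members that fell included fibronectin, Fn1, at 1164 ± 137 and 46.7 ± 8.37 CPM, and Col18a1, which fell by 3.94 on the log2 scale. In the list for secretory load of the endoplasmic reticulum (ER) 22 of 23 members rose and none fell (adjusted p = 1.87e-06, and adjusted p = 0.758 with an estimated correlation). The calcium-binding chaperone Calr went from 628 ± 19.3 to 3387 ± 155 CPM, the ER chaperone Hsp90b1 from 774 ± 5.85 to 3374 ± 62.0 CPM, and the co-chaperone Dnajc3 from 40.5 ± 1.28 to 329 ± 5.24 CPM.

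The genes with the largest changes, taken by a rule fixed before their values were known, were mostly near 0 in the other cell type. On the XEN side, Stra6, the receptor for retinol-binding protein, had 1 count over the ES libraries and 353 ± 32.4 CPM in XEN cells, a ratio of 23810.0 with a counting interval of 4270.0 to 940000. Ugt2b34, a glucuronosyltransferase gene, had 0 counts in every ES library and 59.0 ± 1.76 CPM in XEN cells, so that it was at least 1330.0-fold higher. The aminopeptidase gene Enpep, the gene Glipr1, the adenosine receptor gene Adora1 and Tfec, a relative of Mitf, had 1 or 2 counts over the ES libraries, with ratios from 9705 to 14260. Ctsh, a lysosomal protease gene, rose from 0.0751 ± 0.0699 to 627 ± 26.1 CPM. On the ES side, the glutathione transferase gene Gstp2, Rbmxl2 and Accsl had 0 counts in every XEN library and were at least 2349-fold, 1045-fold and 879.2-fold lower there. Eif2s3y, a Y-linked initiation factor gene, Tcl1, Gdf3 and Mcf2 had 1 or 2 counts over the XEN libraries, with ratios of ES to XEN from 4744 to 8369. Lefty2, a Nodal antagonist, fell from 326 ± 6.51 to 0.0801 ± 0.0724 CPM. Intervals and floors here cover counting error only, and the floor was 3 counts over the group.

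Target genes of signalling and stress pathways changed in both directions, and camera called none of these lists. Of the LIF-STAT3 targets 8 fell, 2 rose and 1 did not pass (adjusted p = 0.28). Bcl3 fell from 46.8 ± 2.68 to 2.93 ± 0.371 CPM and Junb, an AP-1 subunit, rose from 6.82 ± 0.243 to 36.1 ± 1.66 CPM. Of the Wnt-beta-catenin targets 9 fell and 3 rose (adjusted p = 0.127), with Notum, a Wnt deacylase, at 80.2 ± 3.17 and 0.305 ± 0.131 CPM, and Dkk1, a secreted Wnt antagonist, at 0.428 ± 0.0557 and 65.9 ± 1.33 CPM. Of the genes responsive to MEK-ERK signalling, which 2i medium blocks, 11 rose and 4 fell (adjusted p = 0.183). The feedback inhibitor Spry4 rose by a log2 fold change of 4.91 ± 0.18, while Etv5 fell by 2.78. Of the TGF-beta and BMP targets 7 rose and 4 fell (adjusted p = 0.462), with Id2 at 0.931 ± 0.022 and 115 ± 3.55 CPM. Of the HIF targets 12 rose and 4 fell (adjusted p = 0.101), among them the collagen hydroxylase gene P4ha2, which rose by 6.10 ± 0.07, and the demethylase gene Kdm3a, which fell by 1.45. Of the integrated stress response genes 11 fell and 2 rose (adjusted p = 0.229), and Asns, asparagine synthetase, went from 1231 ± 27.2 to 263 ± 50.5 CPM.

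Glycolytic genes changed in both directions. Of 24 members, 11 rose, 10 fell and 3 did not pass (camera adjusted p = 0.901), and fewer rose than fell, 10 against 12, with upper-quartile scaling. Slc16a1, a monocarboxylate transporter that carries lactate and pyruvate, rose from 88.0 ± 2.64 to 1368 ± 38.2 CPM, and neuronal enolase, Eno2, from 4.75 ± 0.0369 to 23.8 ± 0.721 CPM. Pfkp, the platelet phosphofructokinase, fell from 359.5 ± 17.1 to 0.494 ± 0.0451 CPM and the lactate dehydrogenase gene Ldhb from 725 ± 15.7 to 37.1 ± 0.266 CPM. Gapdh fell from 7967 ± 119 to 1361 ± 51.0 CPM, but summed with 30 unnamed models of the same orthology term the counts went from 8372 to 5435 CPM. Of 14 genes for pyruvate entry into mitochondria, 9 fell and 3 rose (adjusted p = 0.245). The kinase gene Pdk1, whose product inhibits pyruvate dehydrogenase, fell from 99.2 ± 2.35 to 14.8 ± 0.596 CPM, the opposing phosphatase gene Pdp2 fell from 27.8 ± 0.891 to 4.32 ± 0.744 CPM, and Pdk2 rose from 10.1 ± 1.18 to 19.1 ± 1.89 CPM. Of 23 genes of the tricarboxylic acid (TCA) cycle, 11 rose and 10 fell (adjusted p = 0.808), with 9 higher and 11 lower under upper-quartile scaling. The malic enzymes Me1 and Me2 rose from 59.1 ± 1.86 to 835 ± 71.8 CPM and from 62.2 ± 1.24 to 392 ± 17.8 CPM, whereas ATP citrate lyase, Acly, fell from 606 ± 13.0 to 271 ± 10.1 CPM.

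The log2 ratio of related metabolic genes changed in 18 of 19 pairs tested with limma, 13 of them by more than 1. Whether the genes of a pair replace each other was not tested. The log2 ratio of Ldha to Ldhb went from -0.17 ± 0.06 to 5.17 ± 0.07 (SD, n = 3; change 5.34 ± 0.08, adjusted p = 1.9e-14 in limma). The log2 ratio of Pfkp to Pfkl, the liver phosphofructokinase, changed by -9.61 ± 0.08 (adjusted p = 1.24e-16 in limma), and Pfkl itself rose from 121 to 393 CPM. The ratio of Cpt1a to Cpt1c changed by -7.00 ± 0.11, that of the acetyl-CoA carboxylases Acaca to Acacb by 4.72 ± 0.10, that of hexokinase Hk2 to Hk1 by 2.07 ± 0.09 and that of the mitofusins Mfn1 to Mfn2 by -1.09 ± 0.08. The ratio of Eno1 to Eno3 did not pass (change -0.10 ± 0.09, adjusted p = 0.292 in limma), and it leaves out 2 unnamed enolase models, at 48.0 CPM together in ES cells and 385 in XEN cells, and other named genes of the orthology term. In XEN cells Pfkp, Cpt1a, Acacb, Cox6a2, Cox4i2 and Pck1 lay under the pseudocount of 1 CPM, so the sizes of these changes depend on it. The last 2 lay under it in ES cells too. The ratios of Cox4i1 to Cox4i2 and of Pck2 to Pck1, both among the 18, therefore follow the first gene and measure no balance. With pseudocounts of 0.1 and 5 CPM the changes were -10.94 and -7.71 for Pfkp over Pfkl, -8.03 and -5.30 for Cpt1a over Cpt1c, and 6.27 and 2.90 for Acaca over Acacb, and at 5 CPM that for Cox6a1 over Cox6a2 turned from 0.72 to -0.007.

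**Figure D2:**
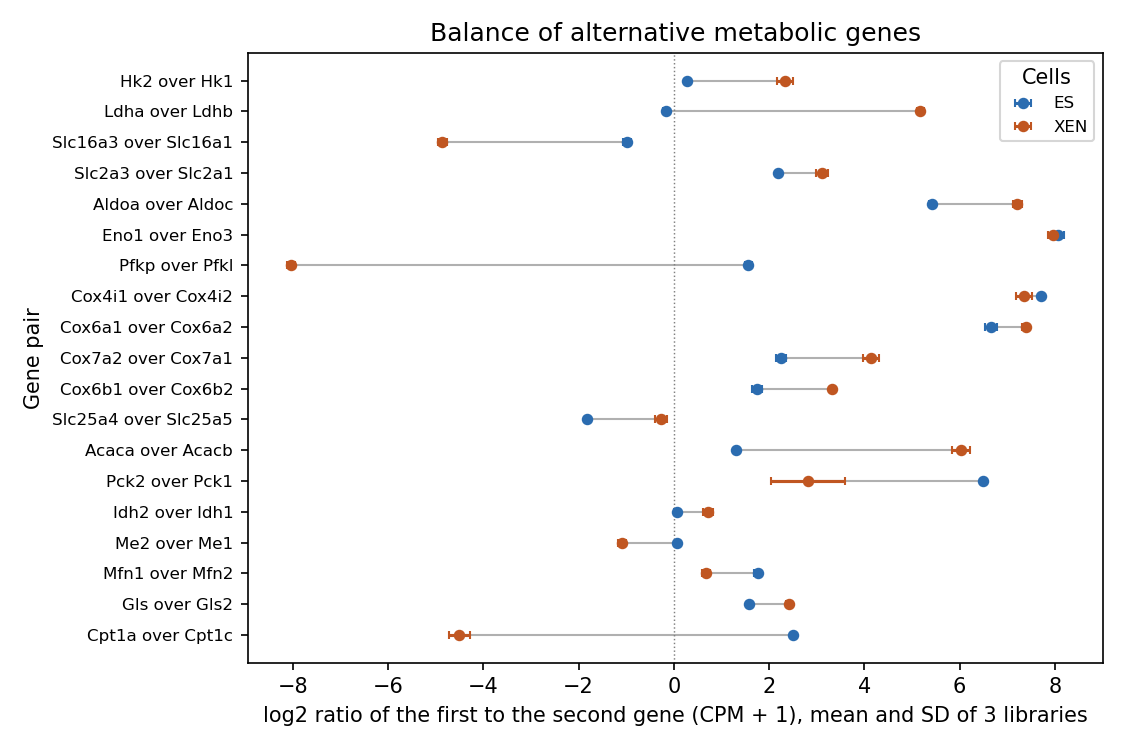
Log2 ratio of the first to the second gene of 19 pairs, from CPM + 1, as mean and SD of 3 libraries in ES cells (blue) and XEN cells (orange), joined by a line. Pfkp over Pfkl changes by -9.61 (-7.71 at a pseudocount of 5 CPM), Ldha over Ldhb by 5.34 and Eno1 over Eno3 by -0.10; Cox6a1 over Cox6a2 changes by 0.72 here and by -0.007 at 5 CPM.

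Genes of the respiratory chain moved in both directions and mostly by less than 2-fold. Of 35 tested nuclear genes of complex I, 14 rose and 15 fell, or 12 and 14 when adjusted over the list alone, and 7 rose and 19 fell with upper-quartile scaling; 0 passed the test against 2-fold. Its subunit genes Ndufb8 and Ndufs3 went from 74.0 ± 3.67 to 142 ± 8.62 CPM and from 49.8 ± 2.13 to 23.6 ± 2.42 CPM. In complex II 3 rose and 3 fell of 8, with 2 and 3 under upper-quartile scaling. In complex III 4 rose and 8 fell of 13, with 2 and 8 under that scaling, and 0 of these 13 passed the test against 2-fold. In complex IV with cytochrome c, 8 rose and 13 fell of 24, with cytochrome c itself, Cycs, rising from 109 ± 3.39 to 276 ± 13.4 CPM and Cox6b2, a variant subunit, falling by 1.54 on the log2 scale. In complex V 6 rose and 7 fell of 17, and Atp5e, the epsilon subunit gene, rose from 3.23 ± 0.225 to 22.9 ± 2.01 CPM. Sdhb fell from 116 ± 3.52 to 61.7 ± 2.59 CPM. Camera called none of the 5 complexes, with adjusted p values of 0.808 for complexes III, IV and V and 0.988 for complexes I and II.

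Genes that maintain and transcribe mitochondrial DNA (mtDNA) fell more often than they rose. Of 17 members, 12 fell and 3 rose (camera adjusted p = 0.28). The ribonucleotide reductase subunit gene Rrm2b fell from 24.96 ± 1.77 to 5.42 ± 0.78 CPM and the mitochondrial thymidine kinase gene Tk2 from 19.96 ± 0.614 to 6.82 ± 1.23 CPM, whereas the polymerase gene Polg rose from 69.8 ± 1.8 to 162 ± 6.23 CPM and the topoisomerase gene Top1mt from 5.31 ± 0.394 to 27.3 ± 0.37 CPM. Of the 76 mitochondrial ribosome genes 35 rose and 31 fell, but 26 rose and 37 fell with upper-quartile scaling, and of 27 import genes 11 rose and 9 fell, or 11 and 12 with that scaling (both adjusted p = 0.808). Mrps2 fell by 1.64 on the log2 scale and Timm21 rose by 2.23 ± 0.09. Of 14 fusion genes 6 rose and 6 fell, or 6 and 8 with upper-quartile scaling (adjusted p = 0.958), and of 12 fission genes 7 rose and 3 fell (adjusted p = 0.495). Of 15 biogenesis regulators 5 rose and 8 fell (adjusted p = 0.968), with Myc at 6.62 ± 0.669 and 65.8 ± 3.87 CPM. Of 26 mitophagy and autophagy genes 13 rose and 10 fell, or 11 and 13 with upper-quartile scaling (adjusted p = 0.808), with the kinase gene Ulk1 falling by 2.47 on the log2 scale. Of 27 antioxidant genes 11 rose and 13 fell (adjusted p = 0.808), with the mitochondrial superoxide dismutase gene Sod2 at 326 ± 7.62 and 54.1 ± 0.707 CPM, and the secreted peroxidase gene Gpx3 at 7.91 ± 1.39 and 547 ± 29.6 CPM. Of 9 uncoupling proteins and carriers 2 rose and 4 fell (adjusted p = 0.808), with Ucp2 falling by 1.84 and the adenine nucleotide carrier gene Slc25a4 rising by 1.15 ± 0.05.

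No mtDNA-encoded gene was listed by symbol. The files held 1 unnamed model annotated as mitochondrial cytochrome c oxidase subunit I, which took 1.90% ± 0.136 of the counts in ES libraries and 1.28% ± 0.014 in XEN libraries (SD, n = 3). The model was 6924 bases long, and whether its counts come from this gene alone was not tested. The difference was -0.621 percentage points, with a two-sided exact permutation p = 0.1, the smallest that 20 arrangements of 3 against 3 libraries allow. In the edgeR fit over all genes the model fell, with a log2 fold change of -0.44 (adjusted p = 1.7e-08), and its share was lower in all 3 XEN libraries than in any ES library.

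**Figure D3:**
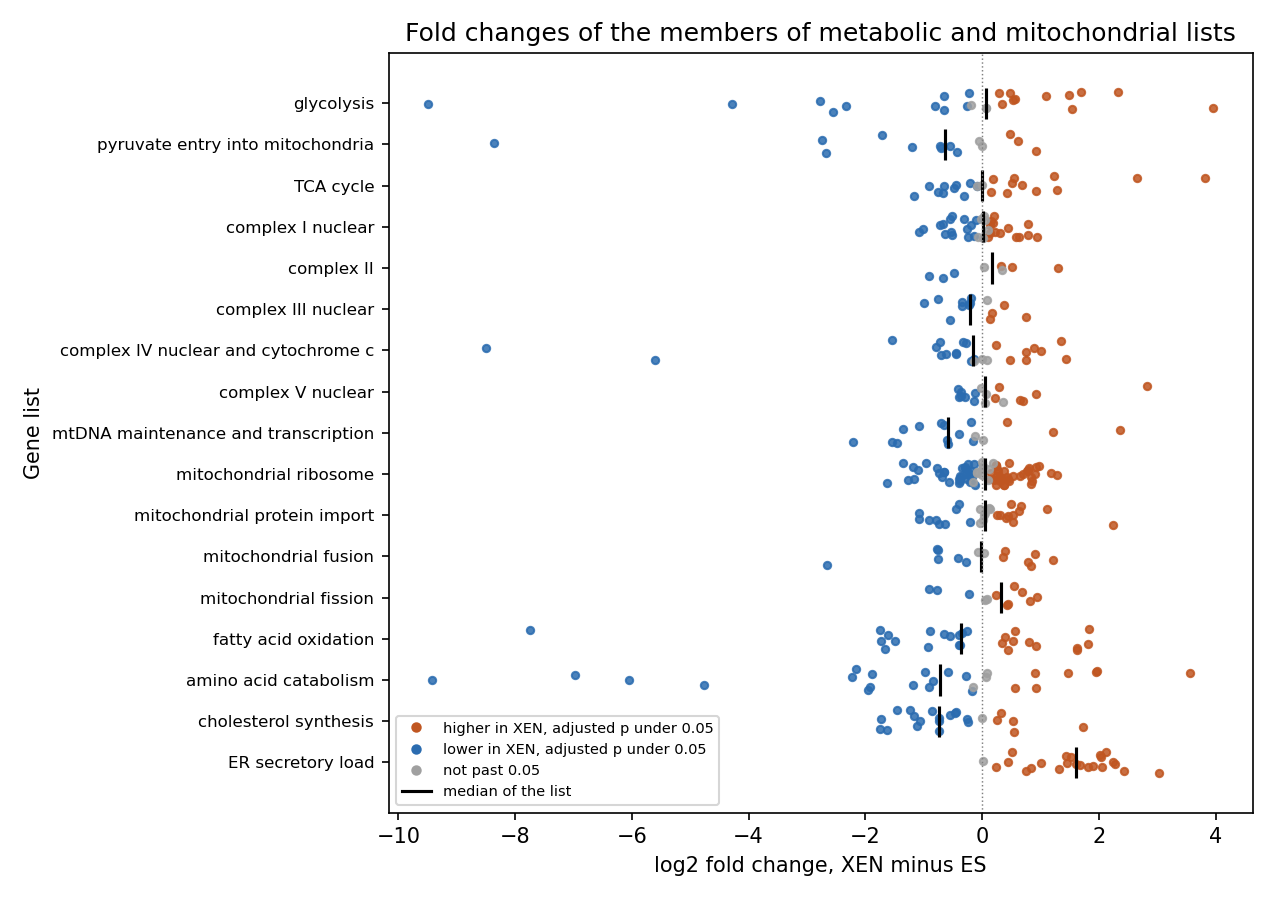
Log2 fold change of each tested member of 17 metabolic, mitochondrial and ER lists, XEN minus ES, with a point per gene coloured by its test at an adjusted p of 0.05 and a bar at the list's median. The median is 1.6 for ER secretory load and -0.577 for mtDNA maintenance, and those of glycolysis, the TCA cycle, complexes I and V, the mitochondrial ribosome and import lie between 0.004 and 0.067 and turn negative with upper-quartile scaling.

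Lipid genes changed both ways. Of 26 fatty acid oxidation genes 15 fell and 11 rose (camera adjusted p = 0.808). Cpt1a, the carnitine palmitoyltransferase that controls fatty acid entry into mitochondria, fell from 175 ± 2.11 to 0.815 ± 0.27 CPM and the dehydrogenase gene Acadm from 203 ± 3.14 to 60.2 ± 2.93 CPM, while Acadvl rose from 13.0 ± 0.638 to 46.1 ± 2.5 CPM. Of 23 cholesterol synthesis genes 17 fell and 5 rose (adjusted p = 0.101), with Idi1 at 159 ± 4.96 and 47.2 ± 2.14 CPM. Insig1, an inhibitor of SREBP processing, rose from 212 ± 9.24 to 702 ± 29.2 CPM. Of 15 fatty acid synthesis genes 8 fell and 5 rose, or 9 and 3 with upper-quartile scaling (camera adjusted p = 0.808). Among them were the elongases Elovl6, which fell by 2.30, and Elovl1, which rose by 2.86 ± 0.05. Of 16 lipoprotein and lipid transport genes 9 rose and 6 fell (adjusted p = 0.462), with the endocytic receptor gene Lrp2 at 2.38 ± 0.137 and 329 ± 67.5 CPM.

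Amino acid, one-carbon and nucleotide genes included some of the largest metabolic changes. Of 26 genes for amino acid catabolism and transport 16 fell and 7 rose (adjusted p = 0.495). Tdh, threonine dehydrogenase, fell from 881 ± 14.7 to 1.26 ± 0.453 CPM and the branched-chain aminotransferase gene Bcat1 from 659.7 ± 7.87 to 5.25 ± 2.29 CPM, whereas glutamine synthetase, Glul, rose by 3.56 ± 0.03 on the log2 scale. Of 20 genes for serine, glycine and one-carbon metabolism 11 fell and 6 rose (adjusted p = 0.808), with Amt, of the glycine cleavage system, at 140.2 ± 6.42 and 0.91 ± 0.261 CPM. Ahcy, the hydrolase of S-adenosylhomocysteine, rose from 15.8 ± 0.247 to 153 ± 6.77 CPM, but summed over all genes of its orthology term, with the copy Gm4737 falling from 514.6 to 215.4 CPM, the counts went from 661.3 to 569.2 CPM. Of 18 nucleotide synthesis genes 9 fell and 6 rose (adjusted p = 0.808), with Impdh1 rising by 3.89 ± 0.07 and Impdh2 falling by 0.86. Of 14 gluconeogenesis and glycogen genes 8 rose and 6 fell, with Gyg, glycogenin, rising by 3.13 ± 0.08, and of 10 pentose phosphate genes 4 rose and 5 fell, with Rpia rising by 1.91 ± 0.06 (adjusted p = 0.808 and 0.988).

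Of 13 genes of DNA methylation and demethylation 6 rose and 7 fell (adjusted p = 0.808). The dioxygenase genes Tet3 and Tet2 went opposite ways, at 2.62 ± 0.144 and 68.6 ± 5.75 CPM against 55.5 ± 3.31 and 3.39 ± 0.986 CPM, and Zfp57, which protects imprints, fell from 431 ± 20.3 to 43.5 ± 0.552 CPM. Of 14 imprinted genes 7 rose and 7 fell (adjusted p = 0.901), with Peg10 at 7.11 ± 0.119 and 670.3 ± 90.3 CPM, and Slc38a4, an amino acid transporter gene with 0 counts in every XEN library, at least 331.5-fold lower there. Of 30 cell cycle genes 16 rose and 11 fell, or 12 and 13 with upper-quartile scaling (adjusted p = 0.808). The D-type cyclin genes moved in opposite directions, with Ccnd2 rising from 0.516 ± 0.159 to 375 ± 11.9 CPM and Ccnd1 falling from 157 ± 3.04 to 2.4 ± 0.111 CPM.

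Markers of other cell types changed in both directions. Of 5 tested neural markers all fell (adjusted p = 0.101), with Ncam1, a cell adhesion molecule, at 63.8 ± 3.07 and 3.07 ± 0.575 CPM. Of 9 trophoblast markers 4 rose and 4 fell (adjusted p = 0.988), with Tead4 at 62.4 ± 1.17 and 103 ± 1.26 CPM and Eomes at 22.2 ± 0.694 and 7.35 ± 0.649 CPM. Of 7 definitive endoderm and gut markers 4 rose and 2 fell, with the claudin gene Cldn6 at 4.39 ± 0.66 and 66.1 ± 4.57 CPM. Of 4 tested fibroblast or feeder markers 3 fell and 1, Pdgfrb, rose from 3.42 ± 0.219 to 7.68 ± 1.1 CPM. Of 3 mesoderm markers 2 fell and 1 rose, with a median log2 fold change of -8.42, or -5.36 with the member at 0 set at its bound. Of 5 blood and macrophage markers 3 rose and 2 fell, with a median of 5.55, or 4.04 at the bound, and Runx1 at 0.953 ± 0.341 and 44.7 ± 1.74 CPM. The adjusted p was 0.808 for the definitive endoderm, mesoderm, blood and primed epiblast lists and 0.599 for the fibroblast list.

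Over all 13581 tested genes, 5707 were higher and 6337 lower in XEN cells at an adjusted p of 0.05 in edgeR, 88.7% together, and 1537 did not pass. Against a change of 2-fold, 2621 were higher and 3175 lower. For 12145 genes, 89.4%, the 3 XEN libraries lay wholly above or below the 3 ES libraries, where chance gives 10%. The log2 CPM of libraries of a group correlated across genes at 0.995, and those of different groups at 0.644 to 0.648, although genes are not independent replicates. Averages of at least 20 CPM in XEN cells with at most 3 counts over the ES libraries were seen for 28 genes, and the opposite for 94. Adjusted over the list alone, the counts equalled those over all genes in every tested list except complex I. Of 49 lists, camera called 5 higher and 1 lower; with an estimated correlation it called 0, and 3 had an unadjusted p under 0.05, while fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 42. The median and mean log2 fold change differed in sign for glycolysis, complex I, mitophagy, gluconeogenesis, pentose phosphate, nucleotide, trophoblast and imprinted genes, and for the fusion genes both were negative while camera ranked the list upward. Upper-quartile scaling moved the median of all genes by -0.147 on the log2 scale, and scaling by library totals alone by -0.133.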

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

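The number of genes past 0.05, 12044, was 12057 with RLE factors, 12152 with upper-quartile factors (41.9% of them higher, against 47.4%), 12154 with library totals only, 13293 with no filter and 11096 with a mean of at least 1 CPM. DESeq2 gave 12407, limma-voom 12051, limma-trend on FPKM 10942, and the replicate block 12000. The number past the test against 2-fold, 5796, ran from 4979 to 6683. Alternatives chosen after the data were seen gave 11680 genes with unnamed models summed into named genes and 11531 with them left out. Leaving out 1 library gave 11911 to 12118 genes, 5633 to 5686 of them higher and 6278 to 6432 lower. Against 2-fold these refits gave 5810 to 5932 genes, 2625 to 2644 higher and 3176 to 3289 lower. They gave 6 to 6 lists, 18 to 18 gene pairs and a difference in the share of the mtDNA-encoded model of -0.692 to -0.557. Of 6 lists called by camera, 0 were called with an estimated correlation, and fry, a test of a list by itself, called 42. The estimated correlation was -0.036 for the naive pluripotency list, below the preset 0.01. A higher correlation was therefore not why this list lost its call. For the 5 lists called higher the estimate was 0.069 to 0.333. With an estimated correlation camera also takes p at the 4 residual degrees of freedom. The lost calls therefore do not show that correlation between genes undoes them. The shares of correlation and of degrees of freedom were not tested. The HIF targets passed (adjusted p = 0.0469) when members under a mean of 5 CPM were left out. Directions turned in fry for the imprinted (adjusted p = 5.29e-05), glycolysis (0.000382), cell cycle (0.0134), trophoblast (0.0258) and pentose phosphate (0.034) lists; the cause was not tested. Dnm1l, at 0.05, turned to -0.102 with upper-quartile factors and to -0.088 with library totals only, which shift all genes downward. The log2 ratio of Cox6a1 to Cox6a2 changed by -0.007 at a pseudocount of 5 CPM, above the level of Cox6a2. At that pseudocount Eno1 over Eno3 passed (-0.17, adjusted p = 0.0271), and at 0.1 CPM Cox4i1 over Cox4i2 did not (-0.50, adjusted p = 0.17). Leaving out 1 library ended calls of named genes, among them Gys1 and Psat1 (each in 4 of 6 refits), and Top2a was called without XEN library A (-0.163). Between the groups, the deviations of libraries with the same letter correlated at 0.033, 0.008 and 0.02, and those with different letters at -0.023 to 0.002. Any effect of the replicate letter was small, but a shared batch is not excluded. Transcript use of Pkm was not run, since the tables used here hold values per gene.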

Other observations

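Except for the splits of the libraries given last, the tests in this section were not among the planned comparisons. The tests of Gapdh copies and of gene blocks on chromosomes 14 and 19 alone were chosen only after their results were seen, and the annotation terms, chromosomes and other copies were taken up after the data had been examined; genes given as examples of annotation terms were chosen after their values were seen. Of 1531 terms of the deposited annotation, camera called 7 higher and 2 lower in XEN cells. With an estimated correlation it called 0 (adjusted p = 0.941 for each of those named here). That run takes p at 4 residual degrees of freedom and adjusts over 1531 terms, so its 0 calls do not decide whether these terms shifted. In the term for cellular response to leukemia inhibitory factor 102 of 115 genes fell and 9 rose (adjusted p = 1.02e-07), with log2 fold changes of -11.52 for Fgf4, a growth factor of epiblast cells, and -9.95 for the transcription factor gene Myb. In the term for piRNA metabolic process all 11 genes fell (adjusted p = 0.0256), with the Tudor domain gene Tdrd12 falling by 8.65. In the term for ER to Golgi vesicle-mediated transport 58 of 75 genes rose and 10 fell (adjusted p = 0.000436), or 53 and 13 with upper-quartile scaling, and the COPII coat gene Sec13 rose by 1.68. In the term for the ubiquitin-dependent ERAD pathway 41 of 53 genes rose (adjusted p = 0.00108), with Edem1, a lectin of ER-associated degradation, rising by 2.55. In the term for hippo signaling 17 of 19 genes rose (adjusted p = 0.00631), with the scaffold gene Amot rising by 6.68 and the kinase gene Lats2 by 5.79. In the term for pancreas development 14 of 16 genes rose (adjusted p = 0.0237), with Ihh, a hedgehog ligand, rising by 9.71 and the homeobox gene Meis2 by 4.04.

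Of genes on the Y chromosome, the ES libraries held 17929 counts and the XEN libraries 5. The helicase gene Ddx3y had 5373 counts over the ES libraries and 2 over the XEN libraries, and the demethylase gene Uty had 2589 and 1. Expression from the Y chromosome thus differs between the lines along with strain, medium and cell type. Whether the XEN line lacks the chromosome was not tested.

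Of 20 chromosomes, 9 had a median log2 fold change apart from that of all genes in a permutation test with 10000 resamples. The test shuffled chromosome labels over genes. Its p-values therefore treat neighbouring genes as independent and do not measure the spread among libraries or lines. Chromosomes 6, 14, 16 and 19 lay 0.414, 0.559, 0.434 and 0.619 above it (adjusted p = 4e-04 for each, from the smallest p possible), by at least 0.402 in each of the 3 XEN libraries, while chromosomes 2, 4, 5, 7 and 17 lay below it, at -0.125, -0.163, -0.111, -0.203 and -0.162 (adjusted p from 4e-04 for chromosome 7 to 0.041 for chromosome 5). The median of all genes, -0.045, includes the 4 higher chromosomes, and genes off them had a median of -0.128. Chromosomes 2, 4, 5, 7 and 17 had medians of -0.17, -0.208, -0.156, -0.248 and -0.207, so part of their shift comes from this reference. For the 4 higher chromosomes, a fit on GC content, transcript length and expression level left shifts of at least 0.36, which argues against these as the cause. Of 16 blocks of their genes, 4 per chromosome in gene order, 13 lay more than 0.2 above all genes and 2 within 0.1. All 8 blocks of chromosomes 14 and 19 were raised, the lowest by 0.337 ± 0.122. This SE comes from resampling the genes of the block and holds no spread among libraries. These 2 chromosomes were singled out after their blocks were seen, and the lowest block lies less than 0.1 above all genes once 2 SE are taken off. Raised blocks were thus spread over the 4 chromosomes, but they do not decide whether a few gene clusters are the cause. Members of the mitochondrial ribosome, respiratory chain and import lists on these chromosomes had a median 0.611 above members elsewhere, with 28 higher and 5 lower against 53 higher and 81 lower, so the near-even counts of these lists join unlike parts; but the chromosomes had been picked because their genes were higher, so this is no separate test, and whether chromosome copy number differs between the lines stays open.

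Gapdh fell by 2.55 on the log2 scale, while its 30 unnamed models rose together from 404.8 ± 29.6 to 4074 ± 106 CPM. Summed over all models the change was -0.623, so reads may have been divided differently between the named gene and its copies. Over 240 orthology terms with an unnamed model, the changes of unnamed models and of the most abundant named gene correlated at 0.035 (Spearman, permutation p = 0.59), which leaves open whether this division is general. Ftl1, a ferritin light chain gene, rose from 2.00 to 2072 CPM while its unnamed models fell from 2875 to 0.366 CPM, and was chosen after its values were seen.

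The 6 libraries can be divided 3 against 3 in 10 ways. The grouping by cell type gave 12044 genes past 0.05 and 5796 past 2-fold, and the highest of the other splits gave 0 and 0, so that 1 and 1 of the 10 splits gave as many. For the lists, the grouping by cell type gave 6 and the highest other split 7, and 5 of 10 splits gave as many. Each other split divides ES and XEN libraries unevenly, so part of the difference between cell types stays in it. The list counts of these splits therefore do not show how many lists are called without such a difference. The 10 splits are too few for a share under 0.05.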
